A study of Mus musculus with 64 samples.

How the data were processed

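RNA was measured in 64 libraries from liver and gonadal adipose tissue of 129S6/SvEvTac mice that had all received inorganic arsenic at 400 ppb in drinking water for 4 weeks, per the labels. The 23 mRNA libraries and 41 small RNA libraries came from wild type (WT) animals and from animals in which the human AS3MT and BORCS7 region stands in place of the mouse As3mt and Borcs7 genes (humanized), in males and females. Liver mRNA libraries were made after ribosomal depletion or after polyA enrichment, adipose mRNA libraries by a published protocol the labels cite, and small RNA libraries with a CleanTag kit, per the labels' protocols. The small RNA libraries fall into 2 sequencing runs, told apart by the form of the library names in the labels. Library names repeat animal tags across tissues, so liver and adipose values were not treated as independent, and no test compared the tissues.

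The 4 tables analysed hold normalized signal as the authors deposited it, made with DESeq2 per the submitters' processing notes. The 2 further tables, of small RNA only, hold values the authors deposited on a regularized log2 scale (rlog) after correction for batch. They served as an alternative. This scale is unlike log2 of the signal plus 1, so a smaller difference on it need not come from the batch correction. The submitters' processing notes also name the mm9 genome build, STAR, Salmon and limma, without versions and without saying which step used which. In each small RNA library the lower signal values, the only ones examined for this, were all whole multiples of 1 step within rounding, and the smallest was 10 steps, so that features with fewer than 10 reads were listed as 0. Dividing by that step gave about 5819450 to 16647100 listed reads per liver library and about 10772200 to 34352700 per adipose library. No such step was derived for the mRNA values, so their reads were not recovered. The normalized mRNA signal summed to about 77307200 to 95381800 per liver library and 83100300 to 90417300 per adipose library.

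Of 48440 gene IDs in the mRNA tables, 48058 matched a name in the gene tables used here (GRCm38.p6), which also gave the order of neighbouring genes. Signal above 0 in any library was listed for 24104 genes in liver and 26841 in adipose tissue, and for 1282 of 1941 small RNA features in liver and 2037 of 2173 in adipose tissue. Forms whose 5′ start is shifted from the annotated one, written with the sign and size of the shift such as _+_1, made up 53.4% and 57.8% of the small RNA features. Near-identical copies cannot be told apart by their values, and their results are given as uncertain between copies.

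Each table was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend) on log2 of the signal plus 1, over features with a mean of at least 10, with 1 model over the 4 groups. The model held the labelled preparation for liver mRNA, the sequencing run for small RNA, and no covariate for adipose mRNA. The 5 comparisons per table were humanized against WT in males, in females and over both sexes, the difference of the genotype differences between the sexes (genotype by sex), and males against females over both genotypes. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are humanized minus WT, male minus female, or the male minus the female genotype difference. Groups are described by mean ± SD of the signal. A feature whose compared groups share no value range in the same direction is called non-overlapping. The share due by chance, given beside such counts, is that of any feature by rank alone. Called features were selected for their difference, so non-overlap is no further support for them.

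For lists, 40 gene lists and 14 miRNA lists were written from memory before the files were opened, and those with at least 5 measured members were tested with camera at its preset correlation of 0.01, with the correlation estimated from the data as an alternative. Members were also adjusted over the list alone. The named genes followed a rule fixed before the data were examined. It took As3mt, Borcs7 and miR-34a, then the 10 largest called and non-overlapping differences in each direction. It also took up to 4 members of each list that was called or held a called member, the 5 smallest p in each direction where a comparison had under 5 calls, and Xist with 4 Y-linked genes as a check of sex. Of the genes this rule took, 3 are not reported here or drawn, though they stayed in every fit and list test.

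The fit and the list test were tested on simulated data with the means and residual spread of the same tables, and with 100 features shifted by 1 and 100 by 2 on the log2 scale. For males it recovered 36% and 79% in liver mRNA, 40% and 55% in adipose mRNA, 49% and 71% in liver small RNA, and 51% and 76% in adipose small RNA. Over both sexes it recovered 58% and 85%, 56% and 80%, 73% and 80%, and 71% and 91% in the same order, so that many differences of 1 would have been missed. False calls numbered 4 to 9 per simulation. A shifted list was found in all 8 simulations, and other lists were called only in liver small RNA (2 and 3). The simulated features were drawn independently, so false list calls that come from correlated members could not show there.

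Alternatives were a pseudocount of 10, no filter, rescaling to a common total, a block for the replicate number, no covariate, the batch-corrected log2 values, the estimated correlation and each library left out in turn. A mean of at least 100 and features without a shifted start were added after the data were seen. Leaving out either WT male of adipose mRNA left a single animal in that group, so the spread in those fits came from the other groups. Counts and adjusted p without those libraries carry that limit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Tests on whole reads were not run. Reads were not recovered for mRNA, and for small RNA they could be recovered only for features with at least 10 reads. The human transgene transcripts and read sequences were not analysed here, because the tables hold mouse features and processed values only.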

Results

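mRNA and small RNA of liver and gonadal adipose tissue were sequenced from WT and humanized mice, all exposed to arsenic, so the comparisons were of genotype and of sex among exposed animals. Liver mRNA came from 3 animals per group, and adipose mRNA from 3 per group except WT males with 2. Small RNA came from 5 WT females, 5 WT males, 5 humanized females and 6 humanized males in liver, and from 5, 4, 6 and 5 in adipose tissue in the same order. Liver small RNA libraries held about 5819450 to 16647100 listed reads and adipose ones about 10772200 to 34352700. Of the genes, 15180 were tested in liver and 17394 in adipose tissue, and of the small RNA features 837 and 1298.

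Whether the mouse genes were gone from the humanized animals was asked first, since As3mt and Borcs7 check the labels. As3mt (ENSMUSG00000003559), which encodes the enzyme that methylates arsenic, had a liver signal of 6014 ± 163 in WT females and 4330 ± 1600 in WT males. Humanized females and males stood at 5.32 ± 0.591 and 1.01 ± 1.00 (log2 difference over both sexes −10.52, limma adjusted p = 5.86e-08). In adipose tissue As3mt stood at 1431 ± 267 and 1432 ± 303 in WT females and males and at 2.07 ± 2.86 and 2.91 ± 0.969 in humanized ones (−8.90, limma adjusted p = 4.17e-05). Borcs7 (ENSMUSG00000062376), a subunit of the complex that positions lysosomes, fell in liver from 783 ± 82.8 to 11.4 ± 3.02 in females and from 668.5 ± 66.6 to 14.2 ± 1.08 in males (over both sexes −5.74, limma adjusted p = 1.13e-07). Adipose Borcs7 fell from 1167 ± 166 to 15.7 ± 2.59 in females and from 1251 ± 363 to 17.8 ± 2.43 in males (−6.08, limma adjusted p = 1.47e-06). Every library matched its genotype label in both genes, and each of these calls held under every alternative.

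Sex was checked with Xist, the RNA that silences 1 X chromosome, and with Y-linked genes. Liver Xist was 49863 ± 10083 in WT females and 50873 ± 3638 in humanized females against 8.68 ± 3.88 and 19.6 ± 20.4 in males (limma adjusted p = 9.53e-08). Liver Ddx3y was 5076 ± 486 in WT males and 5404 ± 732 in humanized males. Adipose Xist was 73144 ± 2270 and 59573 ± 3022 in WT and humanized females against 13.9 ± 12.0 and 6.78 ± 0.774 in males. The remaining Y-linked genes showed a male minus female difference of 9.70 (Kdm5d) in liver, where Eif2s3y and Uty were listed at 0 in humanized females. In adipose tissue they were 11.40 (Ddx3y), 10.68 (Eif2s3y), 10.17 (Kdm5d) and 9.35 (Uty). WT female adipose replicate 5 held a Y-linked trace of 2.46% of the male level, with Ddx3y at 220.

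Which liver genes differed by genotype in males was answered by 5 calls among 15180 genes, 2 higher and 3 lower, all non-overlapping (chance gives 10%). At an unadjusted limma p under 0.05 were 1083 genes, where 759 were due by chance. Beyond As3mt (−11.14, limma adjusted p = 8.71e-07) and Borcs7 (−5.47, limma adjusted p = 4.94e-06), Moxd1 (ENSMUSG00000020000), a monooxygenase-like gene, fell from 8419 ± 6626 to 3.90 ± 2.57 (−10.85, limma adjusted p = 0.00246). This call was lost only without WT male replicate 1 (limma adjusted p = 0.0516, from 0.00105 over the alternatives). Slc22a27 (ENSMUSG00000067656), an organic anion transporter gene that was abundant in females here, rose from 13.1 ± 14.3 to 400 ± 202 (5.40, limma adjusted p = 0.0144). The call was lost under the replicate block and without WT male replicates 1 or 2 or humanized male replicates 1 or 3 (limma adjusted p from 0.000699 to 0.103). Gm6967 (ENSMUSG00000097937), a gene model beside the replaced locus, rose from 3.86 ± 3.97 to 253 ± 99.8 (6.07, limma adjusted p = 0.0387), a call lost under the replicate block and kept, of the 12 libraries, only without WT female replicate 1 or WT male replicates 1 or 3 (limma adjusted p up to 0.295, without humanized male replicate 3). The count was 3 without WT male replicate 1 or humanized male replicate 1 and 15 without WT male replicate 3.

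Sex-biased genes of the male liver were tested as lists. Female-biased liver genes were higher at 23 of 31 members, with a median of 1.66 that was 1.06 without WT male replicate 1 and 0.95 with a pseudocount of 10. Called were 1 over all genes and 10 adjusted over the list alone (camera adjusted p = 1.12e-09, adjusted p = 0.319 with an estimated correlation). Among them the peroxisomal oxidase gene Hao2 went from 9.27 ± 9.49 to 164 ± 90.6 (4.18). The peroxisomal transporter gene Abcd2 went from 288 ± 307 to 2412 ± 1960 (3.47), and A1bg from 15.5 ± 7.09 to 238 ± 107 (3.8). Male-biased liver genes were lower at 24 of 26 members, with a median of −0.90 that was −0.51 without humanized male replicate 1. Called were 1 over all genes and 6 adjusted over the list alone (camera adjusted p = 4.1e-09, adjusted p = 0.319 with an estimated correlation). They included the fatty acid hydroxylase gene Cyp4a12b, 10724 ± 5562 to 761 ± 568 (−4.03), Selenbp2, 114100 ± 75473 to 29724 ± 19375 (−2.16), and the fatty acid elongase gene Elovl3, 13650 ± 5915 to 4068 ± 1719 (−1.78).

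In the same males, lipid synthesis and cell cycle genes were higher and acute phase genes lower. Cholesterol synthesis genes were higher at 24 of 25, with a median of 0.76 that was 0.38 without WT male replicate 2. No member was called (camera adjusted p = 3.85e-08, adjusted p = 0.426 with an estimated correlation). Fatty acid synthesis genes were higher at 19 of 22, with a median of 0.81 that was 0.49 without WT male replicate 1. Members called were 3 adjusted over the list alone and none over all genes (camera adjusted p = 9.94e-08, adjusted p = 0.385 with an estimated correlation). Pnpla3, a lipid droplet acyltransferase and lipase gene, went from 47.9 ± 35.4 to 278 ± 6.98 (2.94). The elongase gene Elovl5 went from 34377 ± 5913 to 64933 ± 8321 (0.91) and Fasn, the fatty acid synthase gene, from 26117 ± 20578 to 58214 ± 5134 (1.51). Cell cycle genes were higher at 27 of 29 (median 0.87, camera adjusted p = 4.79e-10, adjusted p = 0.319 with an estimated correlation). They included the kinase gene Aurkb at 6.34 ± 1.25 and 33.6 ± 16.9 (2.19) and Cdc20 at 29.6 ± 11.9 and 83.1 ± 48.5 (1.63). Acute phase genes were lower at 23 of 23, but their median of −0.88 was −0.01 without WT male replicate 1 (camera adjusted p = 4.78e-10, adjusted p = 0.425 with an estimated correlation).

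Markers of other cell types moved in the same males. T cell genes were higher at 15 of 17 (median 0.74, camera adjusted p = 7.52e-05, adjusted p = 0.365 with an estimated correlation). B cell genes were higher at 15 of 17 (median 0.78, 0.21 without humanized male replicate 3, adjusted p = 0.426 with an estimated correlation). Macrophage genes were higher at 20 of 23 (median 0.37, 0.17 without humanized male replicate 1, 0.60 under the replicate block, adjusted p = 0.497 with an estimated correlation) and endothelial genes at 16 of 18 (median 0.39, 0.20 without WT male replicate 2, adjusted p = 0.425 with an estimated correlation). RNAs without a polyA tail, which a difference in library preparation would move, were lower at 11 of 12 (median −0.51, −0.31 without WT male replicate 2, camera adjusted p = 0.0015, adjusted p = 0.319 with an estimated correlation).

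In the female liver 3 genes were called, 1 higher and 2 lower, all non-overlapping (chance gives 10%). Genes with an unadjusted limma p under 0.05 numbered 859, where 759 were due by chance. As3mt (−9.91) and Borcs7 (−6.02, limma adjusted p = 1.84e-06 for each) were lower. Klk1b22, a kallikrein gene of a family of near copies, rose from a signal listed at 0 to 242 ± 35.9 (limma adjusted p = 0.0255). This call was kept only without WT male replicate 3 or humanized male replicates 2 or 3 and lost without each of the 9 others (limma adjusted p up to 0.476, without humanized female replicate 2). Gm6967 stood at 19.1 ± 10.5 and 366 ± 78.4 (4.32, limma adjusted p = 0.39). Sfxn2, a mitochondrial sideroflexin gene near As3mt but not next to it, stood at 4910 ± 270 and 1893 ± 21.7 (−1.41, limma adjusted p = 0.0506). The steroid hydroxylase gene Cyp17a1 stood at 23263 ± 4233 and 2904 ± 609 (−3.12, limma adjusted p = 0.104). Ces1b stood at 7751 ± 6884 and 37689 ± 4236 (2.57, limma adjusted p = 0.446) and Acp1 at 2628 ± 44.6 and 5097 ± 1187 (0.98, limma adjusted p = 0.5). Chd9 stood at 35719 ± 27275 and 480 ± 74.1 (−6.46, limma adjusted p = 0.222), with Slc1a1 listed at 0 and at 44.7 ± 46.9 (limma adjusted p = 0.39). The count was 6 without WT male replicate 3 and 2 at the lowest.

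Cholesterol synthesis genes in the female liver were lower at 24 of 25 (median −0.81). Adjusted over the list alone 12 were called, and 0 over all genes by limma (camera adjusted p = 1.11e-14, adjusted p = 0.618 with an estimated correlation). Sqle, the squalene epoxidase gene, stood at 8475 ± 3003 in WT and 1788 ± 857 in humanized females (−2.64). Dhcr7 stood at −1.11, Hsd17b7 at −0.81 and Srebf2, the master regulator of this pathway, at −0.59. Fatty acid synthesis genes were lower at 20 of 22 (median −0.42, camera adjusted p = 0.0029, adjusted p = 0.879 with an estimated correlation), with −0.13 without humanized female replicate 2. Neutrophil genes were higher at 10 of 11 (median 2.08, camera adjusted p = 0.000103, adjusted p = 0.722 with an estimated correlation), a median that was 0.32 without humanized female replicate 2. Mpo, myeloperoxidase, stood at 0.292 ± 0.505 and 77.1 ± 66.2 (5.41). B cell genes were higher at 16 of 17 (median 0.87, 0.21 and 1.46 without WT female replicates 2 and 1, 0.49 with a pseudocount of 10, adjusted p = 0.722 with an estimated correlation). Endothelial genes were lower at 15 of 18 (median −0.31, −0.16 without humanized female replicate 2, −0.47 without WT female replicate 1, adjusted p = 0.879 with an estimated correlation). RNAs without a polyA tail were higher at 9 of 12 (median 0.29, 0.55 without WT female replicate 1, camera adjusted p = 0.0106, adjusted p = 0.618 with an estimated correlation).

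Over both sexes 5 liver genes were called, 1 higher and 4 lower, of which 4 did not overlap (chance gives 0.5%). At an unadjusted limma p under 0.05 were 769, where 759 were due by chance. Gm6967 was higher (5.20, limma adjusted p = 0.0126), and As3mt, Borcs7, Moxd1 (overlapping) and Sfxn2 (−1.10, limma adjusted p = 0.0207) were lower. The Gm6967 call was lost under the replicate block and without WT female replicate 1, humanized female replicate 2 or humanized male replicates 1 or 3 (limma adjusted p up to 0.124 over the alternatives). Moxd1 was lost under the replicate block, without the covariate and without WT female replicate 1, WT male replicate 1 or humanized male replicates 1 or 3 (limma adjusted p up to 0.137). The Sfxn2 call was lost after rescaling and under the replicate block and kept, of the 12 libraries, only without WT male replicates 2 or 3 (limma adjusted p up to 0.186). B cell genes were higher at 16 of 17 (median 0.64, camera adjusted p = 3.26e-06, adjusted p = 0.448 with an estimated correlation), with 0.41 without humanized male replicate 3. The count was 2 without humanized male replicate 1 or 3. It was 3 without WT female replicate 1, WT male replicate 1 or humanized female replicate 2, and 7 at the highest.

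**Figure D1:**
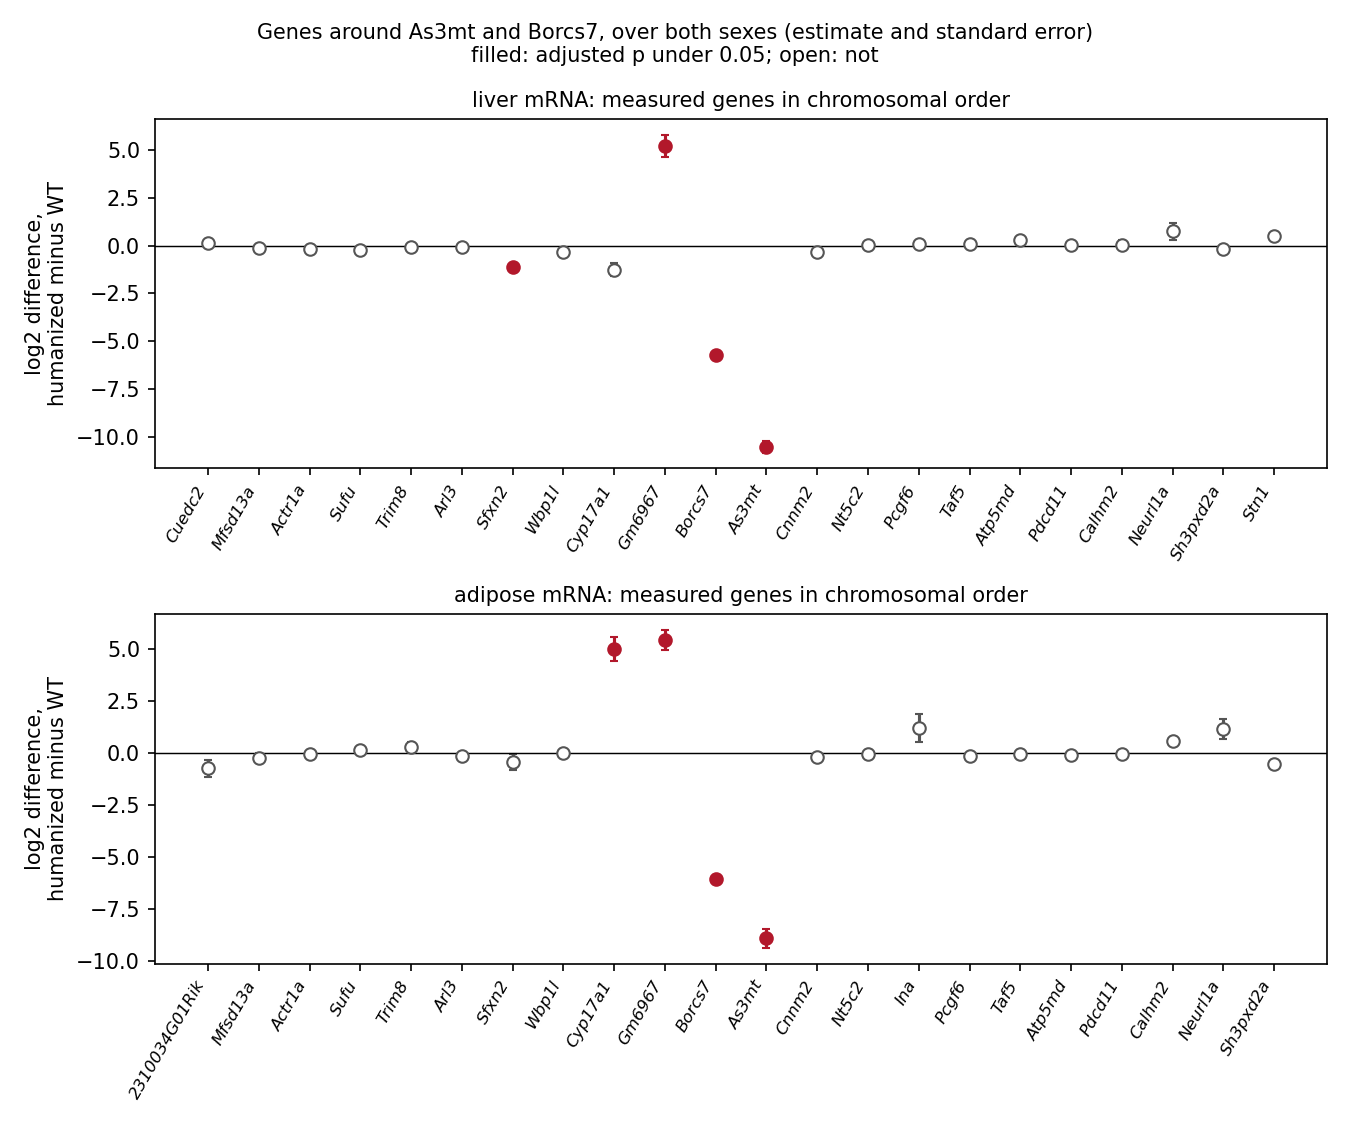
Log2 difference of humanized minus WT animals over both sexes (points, with standard error) for the measured genes around As3mt and Borcs7 in chromosomal order, in liver and adipose tissue, with filled points for an adjusted p under 0.05. As3mt (−10.52 and −8.90) and Borcs7 (−5.74 and −6.08) were low in both tissues, Gm6967 was high (5.20 and 5.42), and Cyp17a1 was high in adipose tissue (4.99).

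Whether the genotype difference itself differed between the sexes was tested in liver for all genes, and 1 gene was called, lower in the male difference. Genes with an unadjusted limma p under 0.05 numbered 1241, where 759 were due by chance. Klk1b22 rose in humanized females and stood at 156 ± 61.5 in WT and 14.5 ± 13.6 in humanized males (limma adjusted p = 0.0157). The call was lost without WT female replicate 2, humanized female replicates 1 or 2 or humanized male replicate 1 (limma adjusted p up to 0.0897). Among the next genes were Pde4b, a cAMP phosphodiesterase gene, at 757 ± 50.2 and 455 ± 28.7 in WT and humanized females and 444 ± 142 and 1324 ± 137 in WT and humanized males (2.36, limma adjusted p = 0.108). Pnpla3 stood at 1478 ± 1061, 377 ± 81.6, 47.9 ± 35.4 and 278 ± 6.98 in the same order (4.53, limma adjusted p = 0.243). Further genes were Slc22a27 (5.17, limma adjusted p = 0.282), Smad6 (1.35, limma adjusted p = 0.426), Cyp17a1 (3.73, limma adjusted p = 0.282) and Moxd1 (limma adjusted p = 0.243), with Rusc2 (−1.22), Usp38 (−1.01) and H4c9 (−1.57, limma adjusted p = 0.585 for these 3). The count was 10 without WT male replicate 3, 0 without the 4 libraries on which Klk1b22 depended, 1 without humanized male replicate 3 and 2 without each of the others.

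Cholesterol synthesis genes differed by genotype in opposite directions in the male and female liver. The difference of differences was above 0 at 25 of 25 genes (median 1.63), 20 of them called when adjusted over the list alone and 0 over all genes by limma. The list had camera adjusted p = 1.56e-18 and adjusted p = 0.448 with an estimated correlation. Single genes were Hmgcs1 at 3.16, Idi1 at 2.50, Mvk at 1.68 and Hsd17b7 at 1.08. Hmgcs1, an early enzyme of the pathway, went from 20248 ± 8407 to 5572 ± 659 in females and stood at 9629 ± 7118 and 23126 ± 15592 in males. Idi1, the isopentenyl diphosphate isomerase gene, went from 13986 ± 4397 to 5305 ± 2047 in females and stood at 10439 ± 5788 and 19914 ± 8208 in males. Fatty acid synthesis genes did likewise at 19 of 22 (median 1.36, adjusted p = 0.448 with an estimated correlation), with Elovl5 at 1.39 and Fasn, 74072 ± 19314 and 40097 ± 9687 in WT and humanized females, at 2.31.

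**Figure D2:**
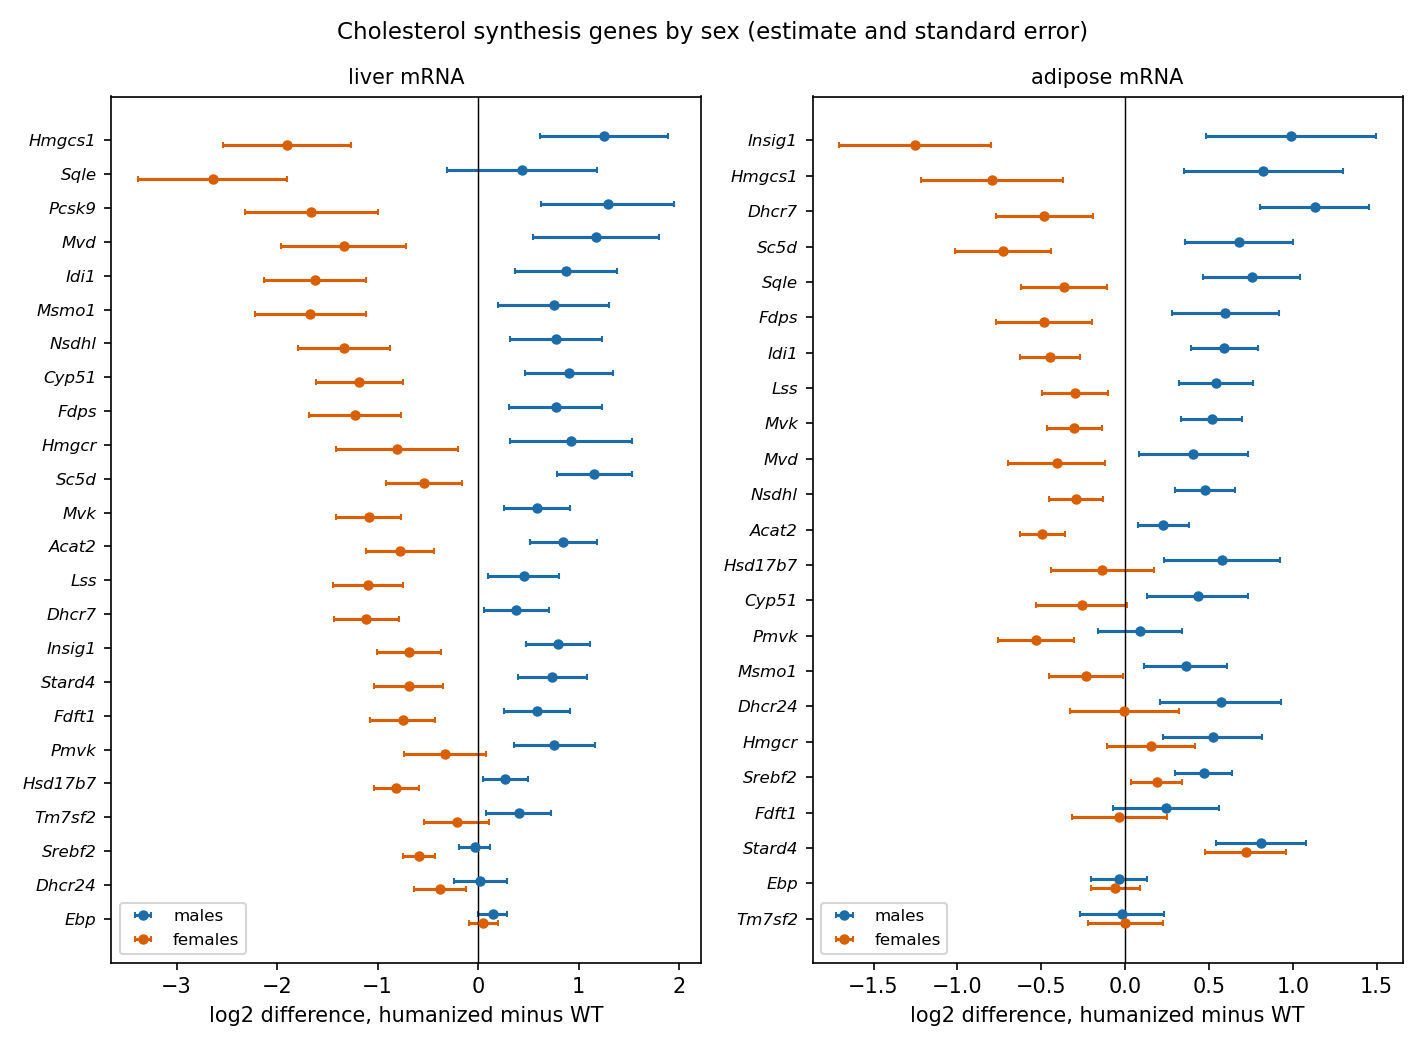
Log2 difference of humanized minus WT animals (points, with standard error) for cholesterol synthesis genes in males and in females, in liver and adipose tissue. Medians were 0.76 in male and −0.81 in female liver and 0.53 in male and −0.30 in female adipose tissue.

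Sex separated the livers most, with 1456 of 15180 genes called, 625 higher in males and 831 lower. Of these 926 did not overlap (chance gives 0.5%), and 3964 genes lay at an unadjusted limma p under 0.05. Higher in males was the urinary protein gene Mup7, 77590 ± 26651 and 53801 ± 46627 in WT and humanized males against 15.9 ± 20.4 and 30.7 ± 11.7 in females (11.87, limma adjusted p = 3.09e-06, uncertain between Mup copies). So were Cyp4a12a, 49225 ± 13182 and 26671 ± 18878 in males (11.75, limma adjusted p = 5.85e-06), Cyp4a12b (humanized females listed at 0), the steroid dehydrogenase gene Hsd3b5 (9.17, limma adjusted p = 9.53e-08), Mup1 (8.05) and Slc22a28 (7.89). Higher in females was the sulfotransferase gene Sult2a1, 25190 ± 21531 and 33032 ± 13265 against 3.08 ± 3.64 and 3.79 ± 5.76 in males (−13.03, limma adjusted p = 1.01e-06). Its relatives were Sult2a2 (−12.73), Sult2a3 (−10.63), Sult2a5 (−10.60) and Sult3a1 (−10.39). Cytochrome genes followed, with Cyp3a41a (239520 ± 23421 and 254540 ± 52031 against 25.1 ± 20.7 and 189 ± 154, −12.21, limma adjusted p = 4.81e-07), Cyp3a41b (−12.41), Cyp3a16 (−12.57) and Cyp2c69 (−11.41), all uncertain between near copies. As3mt was lower in males (−1.17, limma adjusted p = 0.0302), an average that includes the humanized animals near 0 (5.32 ± 0.591 and 1.01 ± 1.00 in females and males, with WT at 6014 ± 163 and 4330 ± 1600). This call was lost with a pseudocount of 10 (−0.51, limma adjusted p = 0.11, the highest over the alternatives) and without 8 of the 12 libraries, each of the females and WT male replicates 1 and 3. The count fell to 854 without humanized female replicate 3, 860 without WT female replicate 3, 883 without humanized male replicate 2, 923 without WT female replicate 1 and 961 without WT female replicate 2.

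Lists of sex-biased liver genes, tested in the same fit, were the only gene lists called with an estimated correlation. Male-biased genes were higher in males at 26 of 26 (25 called over all genes, median 4.79, camera adjusted p = 4.96e-38, adjusted p = 0.012 with an estimated correlation). Female-biased genes had a median of −6.74 over 31 genes, 26 of them called lower and 1 higher over all genes (camera adjusted p = 1.65e-33, adjusted p = 0.012 with an estimated correlation). Endothelial genes were lower in males at 18 of 18 (13 called over all genes, median −0.71, camera adjusted p = 1.01e-09, adjusted p = 0.2 with an estimated correlation), and T cell genes had a median of −0.94 with 7 called over all genes (adjusted p = 0.214 with an estimated correlation).

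In adipose tissue of males 3 genes were called, all lower and all non-overlapping (chance gives 20%). At an unadjusted limma p under 0.05 were 1463, where 870 were due by chance. As3mt (−8.53, limma adjusted p = 0.00244) and Borcs7 (−6.04, limma adjusted p = 6.72e-05) were joined by Rbp7, a retinol-binding protein gene, which fell from 23754 ± 1689 to 6149 ± 797 (−1.96, limma adjusted p = 0.0261). This call was lost under the replicate block (limma adjusted p = 0.158, from 0.00681 over the alternatives) and kept, of the 11 libraries, only without WT female replicates 4 or 5 or humanized female replicate 4. Among those next was Gm6967, 0.502 ± 0.71 to 56.5 ± 19.8 (5.28, limma adjusted p = 0.0624). The calcium sensor gene Stim1 stood at 20782 ± 2350 and 9069 ± 1533 (−1.21, limma adjusted p = 0.0624) and Zbtb7c at 656 ± 136 and 1590 ± 161 (1.29, limma adjusted p = 0.174). Further were the collagen receptor gene Ddr1 (0.87, limma adjusted p = 0.174), Nrcam, 51.4 ± 21.4 to 298.4 ± 150 (2.46, limma adjusted p = 0.182), and Kank2 (0.79, limma adjusted p = 0.187). The count was 7 without WT male replicate 4 and 8 without WT male replicate 5, the only WT males, and 2 at the lowest.

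Cholesterol synthesis genes in male adipose tissue were higher at 22 of 24 (median 0.53). Members called were 1 adjusted over the list alone and 0 over all genes by limma (camera adjusted p = 1.58e-08, adjusted p = 0.721 with an estimated correlation). Extracellular matrix genes were higher at 25 of 28 (median 0.50, camera adjusted p = 0.000223, adjusted p = 0.721 with an estimated correlation), with 0.27 without humanized male replicate 4. Lum, lumican, stood at 2659 ± 124 and 10225 ± 4825 (1.83), while Thbs1, thrombospondin 1, stood at 58110 ± 7403 and 14304 ± 3344 (−2.04). Among genes of fatty acid oxidation, the kinase gene Pdk4, which limits glucose oxidation, stood at 43295 ± 8726 and 7667 ± 1793 (−2.51). Vnn1 stood at 2029 ± 241 and 410 ± 116 (−2.34). Both were called when adjusted over the list alone (list adjusted p = 0.721 with an estimated correlation). Hepatocyte genes were lower at 23 of 23 (median −1.55), a direction that turned to 1.55 without WT male replicate 5 (adjusted p = 0.826 with an estimated correlation). WT males (n = 2) held albumin (Alb) at 65111 ± 90636, an SD above the mean, so these 2 libraries differed widely. WT male replicate 5 also lay apart on principal component 2, an axis of spread among the adipose mRNA libraries. It stood at −120.7 there, and the other libraries ran from −27.8 to 58.5. Erythrocyte genes had a median of −2.24, which was −1.06 without WT male replicate 5 (camera adjusted p = 9.33e-05, adjusted p = 0.721 with an estimated correlation).

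In female adipose tissue 3 genes were called, 1 higher and 2 lower, all non-overlapping (chance gives 10%). Genes with an unadjusted limma p under 0.05 numbered 913, where 870 were due by chance. Gm6967 rose from 0.644 ± 1.11 to 68.8 ± 22.4 (5.56, limma adjusted p = 0.0368). The call was lost without a filter, under the replicate block and without WT female replicates 4 or 5, any humanized female or humanized male replicates 5 or 6 (limma adjusted p up to 0.406, without humanized female replicate 6). As3mt (−9.27, limma adjusted p = 0.000411) and Borcs7 (−6.13, limma adjusted p = 2.05e-05) were lower. Cyp17a1 stood at 5.77 ± 5.35 in WT and 337.5 ± 87.5 in humanized females (5.97, limma adjusted p = 0.118) and Plaat1 at 63.0 ± 22.3 and 2.86 ± 3.62 (−4.39, limma adjusted p = 0.593). The other small p-values were of Anxa3 at 0.79, Gm10384 at 3.19, Cpq at 0.50, Gadd45gip1 at −0.60 and Scoc at −0.95 (limma adjusted p = 0.593, 0.71, 0.796, 0.49 and 0.49). The count was 5 without WT female replicate 5, 6 without humanized male replicate 4, 7 without WT male replicate 4, 8 without WT male replicate 5 and 2 at the lowest. Mesothelial genes were higher at 15 of 15 (median 1.30, camera adjusted p = 1.18e-06, adjusted p = 0.511 with an estimated correlation), with 0.69 without WT female replicate 4. Cholesterol synthesis genes were lower at 20 of 24 (median −0.30, camera adjusted p = 6.74e-05, adjusted p = 0.511 with an estimated correlation), with −0.18 without WT female replicate 6. Thermogenic genes, with the coactivator gene Ppargc1b at 1008 ± 286 and 461 ± 51.6 (−1.10, adjusted over the list alone), were lower at 16 of 17 (median −1.10), but their median turned to 0.12 without WT female replicate 4 (camera adjusted p = 9.63e-05, adjusted p = 0.511 with an estimated correlation).

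Over both sexes 4 adipose genes were called, 2 higher and 2 lower (1 and 2 after rescaling), all non-overlapping (chance gives 1%). At an unadjusted limma p under 0.05 were 1236, where 870 were due by chance. Gm6967 was higher (5.42, limma adjusted p = 0.00366) under every alternative. Cyp17a1, which makes androgen precursors in gonad and adrenal, rose from 5.77 ± 5.35 to 337.5 ± 87.5 in females and from 21.5 ± 22.6 to 275 ± 130 in males (4.99, limma adjusted p = 0.048). This call was lost without a filter and after rescaling, and was kept, of the 11 libraries, only without WT female replicate 6 or WT male replicate 5 (limma adjusted p up to 0.249, without humanized female replicate 6). Next were the matrix gene Cilp (1.51), Zbtb7c (0.90), Hpgd, the prostaglandin dehydrogenase gene (−0.74), with limma adjusted p = 0.216 for these 3. Pdgfrl (2.10, limma adjusted p = 0.295) followed, with Dctn3 (−0.62, limma adjusted p = 0.104) and Rbp7 (−0.93, limma adjusted p = 0.216). Extracellular matrix genes were higher at 26 of 28, with a median of 0.38 that was 0.25 without WT male replicate 5. Adjusted over the list alone 5 were higher and 1 lower, and 0 over all genes by limma (camera adjusted p = 1.13e-06, adjusted p = 0.732 with an estimated correlation). They included Fn1, fibronectin, 41795 ± 13024 to 57363 ± 5966 in females and 46654 ± 2240 to 85495 ± 14487 in males (0.68). Mmp2, a gelatinase gene, went from 6608 ± 1669 to 9957 ± 450.1 and from 5200 ± 1145 to 11484 ± 5607 (0.84), with Loxl1 (0.67) and Lum (1.08). Genes of fatty acid oxidation were lower at 27 of 28 (median −0.32, camera adjusted p = 1.13e-06, adjusted p = 0.442 with an estimated correlation), with −0.19 without WT female replicate 4 and Pdk4 at −1.53. The count was 7 without WT male replicate 5 and 3 at the lowest.

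Genotype by sex gave 0 calls in adipose tissue (smallest limma adjusted p = 0.209). Genes with an unadjusted limma p under 0.05 numbered 1183, where 870 were due by chance. The smallest p-values belonged to Rbp7 (−2.05) and the transcription factor gene Mafk (−1.16), both at limma adjusted p = 0.209. Next came Tead4 (−1.85), the small heat shock gene Hspb1 (−1.06) and Stim1 (−1.26), all at limma adjusted p = 0.32. Mid1ip1, which aids fatty acid synthesis, stood at 0.90 (limma adjusted p = 0.407). Further were Prrg1 (0.96), Gm10044 (7.09), Gm3468 (7.94) and Gm18336 (3.48), all at limma adjusted p = 0.44. For cholesterol synthesis genes the difference of differences was above 0 at 23 of 24 (median 0.75). Members called were 10 adjusted over the list alone and 0 over all genes by limma (camera adjusted p = 1.01e-11, adjusted p = 0.788 with an estimated correlation). Idi1 (1.04), Dhcr7 (1.61) and Acat2 (0.72) were among those leading it. Dhcr7, the last enzyme of the pathway, stood at 1473 ± 155 and 1058 ± 147 in WT and humanized females and 825 ± 202 and 1909 ± 924 in males. Marker lists of other cell types moved in the same comparison (medians of erythrocyte −2.62, mesothelial −2.06, hepatocyte −1.72 and T cell genes 1.02). How these depend on single libraries is given below. The count was 1 without humanized male replicate 4, 3 without WT female replicate 5 and 6 without WT male replicate 4.

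Sex separated adipose tissue by 73 genes, 27 higher in males and 46 lower. Of these 68 did not overlap (chance gives 1%), with 2181 at an unadjusted limma p under 0.05. Gonadal fat lies beside different organs in males and females, so sex and the site of the fat cannot be told apart here. Among the largest called differences were Hox genes, which set position along the body axis. Hoxa10 stood at 1222 ± 93.8 and 1110 ± 213 in WT and humanized females against 3.18 ± 1.55 and 3.96 ± 5.08 in males (−8.32, limma adjusted p = 0.00011). Hoxc10 stood at 2426 ± 327 and 2275 ± 246 against 20.1 ± 11.2 and 24.9 ± 27.3 (−7.34, limma adjusted p = 0.00692). Hoxa11 stood at 485 ± 41.2 and 448 ± 182 against a signal listed at 0 and 1.08 ± 1.87 (limma adjusted p = 3.94e-05). Hoxa13 stood at 245 ± 70.9 and 136 ± 76.8 and Hoxa11os at 331 ± 109 and 262 ± 130, both with males listed at 0. Hoxc11 and Gm29650, the latter higher in males, also held a group listed at 0. Among those higher in males was Gm29650 (limma adjusted p = 0.000284). Lost without several libraries, WT male replicate 4 among them, were the estrogen sulfotransferase gene Sult1e1 (6.40, limma adjusted p = 0.0372), Slc38a5 (4.02, limma adjusted p = 0.0239), Pde11a (3.44, limma adjusted p = 0.0393) and Serpina1b (3.03, limma adjusted p = 0.0391). Pgr, the progesterone receptor gene, stood at 78.3 ± 98.8 and 387 ± 421 in females with males listed at 0, a call lost with a pseudocount of 10 and without 6 of the 11 libraries. The count was 39 without humanized male replicate 6, 44 without WT female replicate 6 or humanized female replicate 5, 48 without WT male replicate 4 and 91 at the highest.

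**Figure D3:**
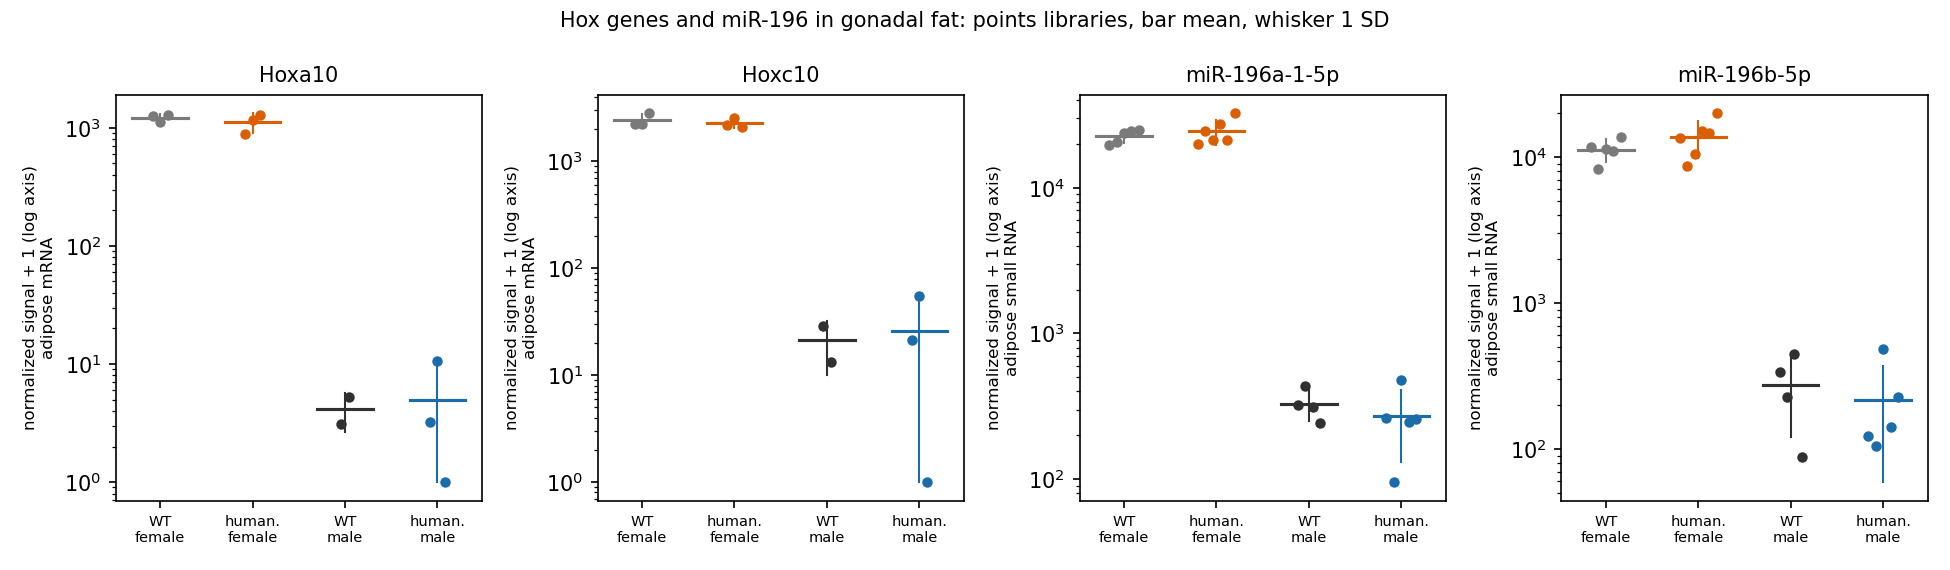
Signal plus 1 on a log axis in each adipose library (points) with group means (bars) and 1 SD (whiskers) for Hoxa10, Hoxc10, miR-196a-1-5p and miR-196b-5p in WT and humanized females and males. All 4 were high in females, with Hoxa10 at 1222 ± 93.8 and miR-196b-5p at 11187 ± 1985 in WT females against 3.18 ± 1.55 and 273 ± 153 in WT males.

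Genotype gave 0 calls in liver small RNA in males (46 of 837 features at an unadjusted limma p under 0.05 where 42 were due by chance, smallest limma adjusted p = 0.635). miR-34a-5p, a p53-induced miRNA, stood at 1285 ± 714 in WT and 3065 ± 1692 in humanized males (1.28, limma adjusted p = 0.847). miR-298-5p stood at 19.8 ± 7.67 and 3.38 ± 8.27 (limma adjusted p = 0.635), with 5 of the 6 humanized males listed at 0, so that its fold is not given. Further were miR-137-3p at 0.76, miR-145-3p at −0.57 and miR-215-5p, another p53-induced miRNA, at −1.11 (limma adjusted p = 0.847 for these 3). The count was 1 without humanized male replicate 5.

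In females genotype gave 0 calls in liver small RNA (25 at an unadjusted limma p under 0.05 where 42 were due by chance, smallest limma adjusted p = 0.656). Over both sexes it gave 0 (26, smallest limma adjusted p = 0.828), and by sex 0 (25, smallest limma adjusted p = 0.965). miR-34a-5p stood at 2114 ± 661 in WT and 1108 ± 524 in humanized females (−1.04, limma adjusted p = 0.998). Its genotype by sex difference was 2.33 (limma adjusted p = 0.965), 2.71 within run A and 2.05 within run B. miR-151-5p stood at 5605 ± 873 and 7059 ± 915 (0.34, limma adjusted p = 0.656) and the inflammation-linked miR-146a-5p at 11720 ± 2918 and 21560 ± 5752 (0.86, limma adjusted p = 0.998). By sex miR-221-3p stood at 0.33 (limma adjusted p = 0.965, as for miR-298-5p). The Dlk1-Dio3 miRNAs, an imprinted cluster, were higher over both sexes at 18 of 20 (median 0.38, adjusted p = 0.823 with an estimated correlation), with 0.22 without WT male replicate 4 and 0.06 with the batch-corrected values.

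Sex gave 77 calls in liver small RNA, 43 higher in males and 34 lower (43 and 21 after rescaling). Of these 5 did not overlap (chance gives 0.00172%), with 200 at an unadjusted limma p under 0.05. miR-592-5p was 48.95 ± 16.8 and 25.8 ± 6.62 in WT and humanized males against 2.66 ± 5.95 and a signal listed at 0 in females (limma adjusted p = 2.38e-06). Its shifted form miR-592-5p_+_1 was 1385 ± 700 and 811 ± 158 against 98.6 ± 127 and 83.9 ± 45.8 (3.89, limma adjusted p = 1.57e-06). The level of miR-149-5p was 141 ± 89.1 and 159 ± 45.99 against 29.1 ± 8.06 and 30.1 ± 14.6 (2.25, limma adjusted p = 1.08e-05). miR-674-5p (−0.58, limma adjusted p = 0.00211) and miR-152-3p (−0.39, limma adjusted p = 0.00428) were lower in males. Dlk1-Dio3 miRNAs were higher in males at 19 of 20, with a median of 1.31 that was 0.32 with the batch-corrected values. Called were 8 over all features and 16 adjusted over the list alone (adjusted p = 0.383 with an estimated correlation), led by miR-541-5p (1.45), miR-409-3p (1.5), miR-411-5p (1.22) and miR-434-3p (1.04). The count was 50 without humanized female replicate 4 and 135 without WT female replicate 2.

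In adipose small RNA 8 features were called by genotype in males, 1 higher and 7 lower. Of these 2 did not overlap (chance gives 1.59%), with 199 at an unadjusted limma p under 0.05 where 65 were due by chance. The erythrocyte miRNA miR-486-3p fell from 3170 ± 1818 to 722 ± 245 (−2.04). Also lower were miR-486-5p (−1.66) and miR-3107-5p, which shares its mature sequence and went from 202160 ± 109070 to 59337 ± 17666 (−1.66), uncertain between copies, with their shifted forms miR-486-5p_+_2 (−1.61) and miR-3107-5p_+_2 (−1.63). Also called were miR-320-3p_+_1, 1900 ± 560 to 1032 ± 215 (−0.89), and let-7d-3p_+_1 (−0.92). The only higher one was miR-195-3p_+_1, and all 8 had limma adjusted p = 0.0487. In miR-195-3p_+_1 WT male replicates 6 and 9 were listed at 0, which stands for fewer than 10 reads. WT male replicates 11 and 12, at 17.9 and 23.9, lay within the range of the humanized males. Whether miR-195-3p_+_1 rose is therefore uncertain. The count was 0 without WT female replicates 6, 10 or 11, WT male replicates 6, 9 or 11, humanized female replicate 8 or any humanized male. It was also 0 without a filter, under the replicate block, after rescaling, without the run covariate and without shifted forms. It was 1 without humanized female replicate 9, 13 without humanized female replicate 6 and 25 without WT male replicate 12. miR-34a-5p stood at 24041 ± 5178 and 30758 ± 6918 (0.31, −0.44 under the replicate block, limma adjusted p = 0.728). The hepatocyte miRNA mmu-mir-122-5p stood at 307290 ± 257040 and 76051 ± 28872 (−1.79, limma adjusted p = 0.0522). Erythrocyte miRNAs were lower at 5 of 5 (2 called over all features, median −1.46, −1.003 without WT male replicate 11, adjusted p = 0.156 with an estimated correlation). Dlk1-Dio3 miRNAs were higher at 52 of 58 (median 0.44, 0.22 with the batch-corrected values, camera adjusted p = 7.81e-09, adjusted p = 0.344 with an estimated correlation). Adjusted over the list alone 4 were called, and 0 over all features by limma, namely miR-380-3p (1.09), miR-329-5p (0.90), miR-337-3p (2.41) and miR-380-5p (1.23). WT male replicates 6 and 9 were listed at 0 in miR-337-3p, so the size of its difference is uncertain.

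In females genotype gave 0 calls in adipose small RNA (32 at an unadjusted limma p under 0.05 where 65 were due by chance, smallest limma adjusted p = 0.998). Over both sexes it gave 0 (180, smallest limma adjusted p = 0.115) and by sex 0 (63, smallest limma adjusted p = 0.313). miR-34a-5p stood at 25878 ± 12368 in WT and 13578 ± 5911 in humanized females (−0.85, limma adjusted p = 0.998), with a genotype by sex difference of 1.16 (limma adjusted p = 0.86), 1.68 within run A and 0.75 within run B. Over both sexes miR-486-3p stood at −1.29 (limma adjusted p = 0.115), miR-329-5p at 0.65 and miR-380-3p at 0.71 (limma adjusted p = 0.124), both of the Dlk1-Dio3 cluster. By sex mmu-mir-34c-3p, of the p53-induced miR-34 family, had limma adjusted p = 0.313, with WT females at 243 ± 440 (1031 in replicate 10 and 39.1 to 54.9 in the others), humanized females at 23.9 ± 19.9, WT males listed at 0 and humanized males at 23.0 ± 17.6. Dlk1-Dio3 miRNAs were higher over both sexes at 55 of 58 (median 0.38, 0.18 with the batch-corrected values, camera adjusted p = 8.24e-15, adjusted p = 0.188 with an estimated correlation). Let-7 miRNAs, which restrain growth genes, were lower over both sexes at 12 of 17 (median −0.19, −0.08 after rescaling, 5 adjusted over the list alone and 0 over all features by limma, adjusted p = 0.0451 with an estimated correlation). The count over both sexes was 8 without WT male replicate 12.

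Sex gave 130 calls in adipose small RNA, 56 higher in males and 74 lower (30 and 81 after rescaling). Of these 12 did not overlap (chance gives 0.00344%), with 364 at an unadjusted limma p under 0.05. As for mRNA, sex and the site of the gonadal fat cannot be told apart. Features of the miR-196 family, which lies in the Hox clusters, were far higher in females. miR-196a-2-5p stood at 34419 ± 2686 and 37202 ± 6913 in WT and humanized females against 472.5 ± 104 and 396 ± 223 in males (−6.47, limma adjusted p = 1.3e-14). The copy miR-196a-1-5p, not surely told apart, stood at 22573 ± 2306 and 24459 ± 4671 against 328 ± 78.5 and 268 ± 138 (−6.39). For miR-196b-5p the signal was 11187 ± 1985 and 13715 ± 3900 against 273 ± 153 and 214 ± 156, with miR-196b-3p listed at 0 in males. miR-344d-1-3p was lower in males (−4.27, limma adjusted p = 0.000429), a size that is uncertain because several males of each genotype were listed at 0. Erythrocyte miRNAs were higher in males at 5 of 5 (4 called over all features, median 1.35, adjusted p = 0.35 with an estimated correlation), with miR-144-3p at 1.60 and miR-486-5p at 1.28. Other lists were lower in males, epithelial miRNAs at 12 of 12 (2 called over all features, median −1.12, −0.71 without WT female replicate 10, −0.58 with the batch-corrected values, adjusted p = 0.367 with an estimated correlation) and Dlk1-Dio3 miRNAs at 56 of 58 (7 called, median −0.34, −0.15 with the batch-corrected values, adjusted p = 0.367 with an estimated correlation). Adipose-enriched miRNAs were lower at 23 of 26 (7 called, median −0.33, −0.20 with the batch-corrected values, adjusted p = 0.35 with an estimated correlation). The miR-34 and ciliated cell miRNAs, lower at 6 of 7, were not called as a list at the preset correlation either (camera adjusted p = 0.0623, adjusted p = 0.437 with an estimated correlation). Their median was −1.13, and −0.63 without WT female replicate 10. The count was 73 without WT male replicate 6, 81 without WT female replicate 6 and 161 at the highest. Rescaling moved the median of all features by 0.16 in males, 0.11 over both sexes and 0.11 by sex in adipose small RNA, and by 0.10 for liver mRNA in males.

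**Figure D4:**
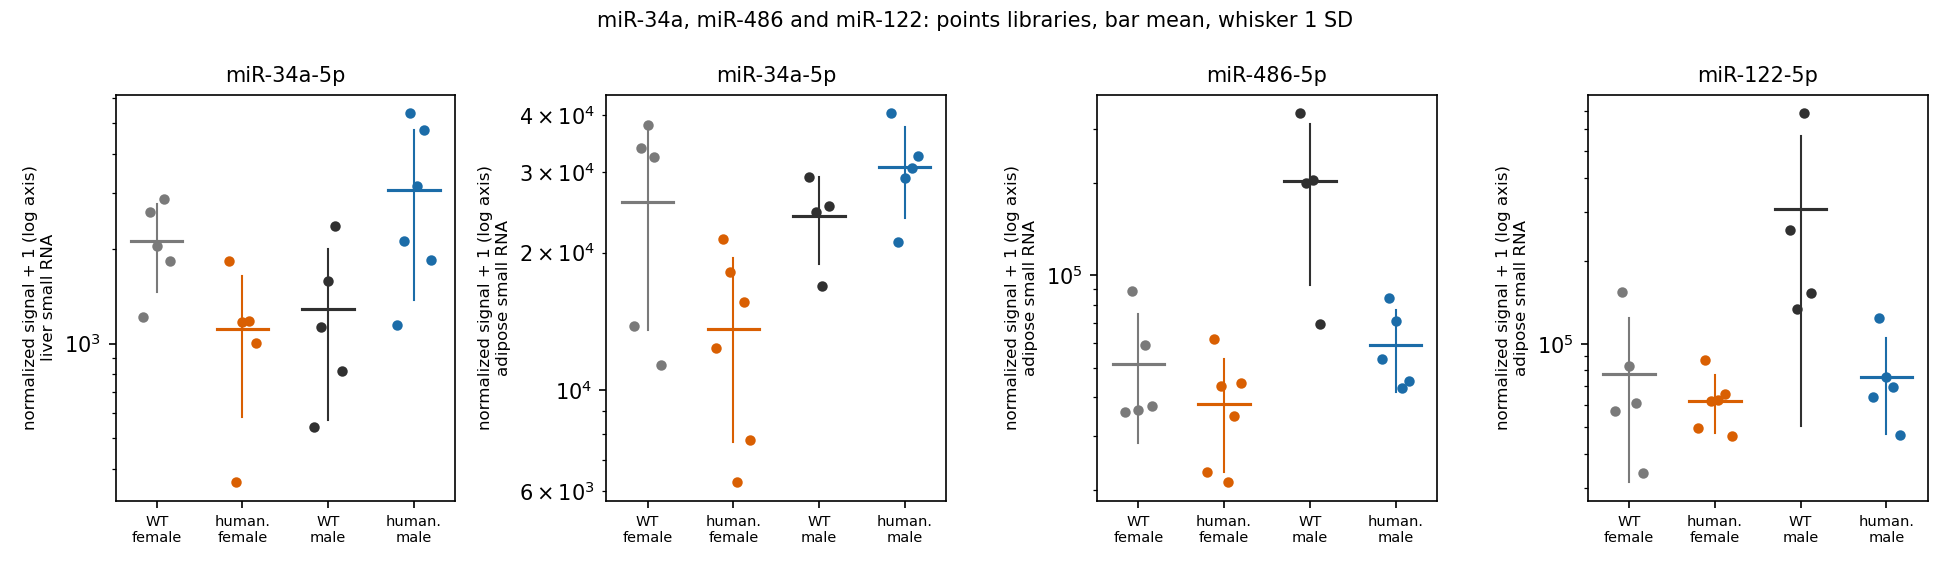
Signal plus 1 on a log axis in each library (points), with group means (bars) and 1 SD (whiskers) for miR-34a-5p in liver and for miR-34a-5p, miR-486-5p and miR-122-5p in adipose tissue, in WT and humanized females and males. Liver miR-34a-5p stood at 2114 ± 661 in WT and 1108 ± 524 in humanized females and at 1285 ± 714 and 3065 ± 1692 in males, and adipose miR-122-5p at 307290 ± 257040 in WT males and 76051 ± 28872 in humanized males.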

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

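Chosen only after the results were seen were the tests of reads from the human insert and of an effect near the replaced locus, all 3 tests of the cholesterol synthesis genes, and the test of single libraries for miR-486 and miR-122. Explanations for the sex-biased liver genes of humanized males were drafted as well, were replaced by those for the cholesterol synthesis genes and were not tested here.

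Genes near the replaced locus stood apart in humanized animals, with Gm6967 at 5.20 in liver and 5.42 in adipose tissue, Cyp17a1 at 4.99 in adipose tissue and Sfxn2 at −1.10 in liver over both sexes. Reads of the human insert assigned to a mouse gene could only raise it, which argues against this source for Sfxn2 (−1.10), though its call was lost after rescaling, under the replicate block and without 10 of the 12 libraries. For Gm6967 and Cyp17a1 this source cannot be told apart from a true rise, since the lower value of Cyp17a1 in liver (−1.26) was not called and read sequences were not analysed here. That value averages 0.61 in males and −3.12 in females (limma adjusted p = 0.792 and 0.104). Added reads would not make the female fall, but it was not called either. An effect near the replaced locus cannot be told apart either, since the windows of 20 neighbouring genes that held 2 called ones, 0.121% in liver (17 of 14060) and 0.119% in adipose tissue (19 of 15937), all held these same neighbours. Leftover sequence of another strain around the locus remains possible and was not tested.

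Cholesterol synthesis genes were higher in humanized males and lower in humanized females, with genotype by sex medians of 1.63 in liver and 0.75 in adipose tissue, though neither list was called with an estimated correlation (adjusted p = 0.448 and 0.788). Without any 1 library these genotype by sex medians kept at least 80.3% of their size (1.31 in liver without WT female replicate 2). One library is therefore not a likely source of them. This does not hold for each sex alone. In male liver a median of 0.76 became 0.38 without WT male replicate 2. In female adipose tissue −0.30 became −0.18 without WT female replicate 6. Unequal library preparation in liver cannot be told apart, since the labels that gave medians of 1.35 within ribosomal depletion and 1.62 within polyA libraries separated 0 genes by limma (659 at an unadjusted limma p under 0.05), and RNAs without a polyA tail stood at −0.91 in genotype by sex. A different time of collection cannot be told apart, since 15% of the clock genes differed in genotype by sex in adipose tissue (3 of 20 at an unadjusted limma p under 0.05) and 10% in liver (2 of 20). Over all genes 1183 of 17394 in adipose tissue and 1241 of 15180 in liver lay under the same threshold. These few clock genes thus point neither way. A response of the pathway to feeding or body weight might also differ between the groups and could not be tested.

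miR-486 and miR-122 were lower in humanized male adipose tissue, with miR-486-5p at −1.66 and miR-122-5p at −1.79, with the call of miR-486-5p lost without 13 of the 20 libraries. Less blood may explain miR-486, since miR-451, the main erythrocyte miRNA, stood at −1.46. Less liver RNA cannot be told apart for miR-122, since 5 other features abundant in liver had a median of −0.72 (miR-802-5p −1.43, miR-192-5p −1.17, miR-31-5p −0.72, miR-194-1-5p −0.64 and miR-194-2-5p −0.63), while a wider set of 11 ran up to 0.86 (miR-455-5p). The sequencing runs are not a likely source, since the smallest of the differences within a run was −1.14. One library is not a likely source, since at least 69.1% of each difference stayed without any 1 male library (without WT male replicate 11, miR-122-5p).

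In 84 groups examined for outlying libraries with Dixon's test, which by chance marks about 1 in 20 groups (4.2 here), 3 libraries stood out. They were humanized female liver replicate 5 in miR-149-5p (55.8, the nearest at 27.5), WT female liver replicate 2 in miR-592-5p (13.3, the others listed at 0) and humanized male adipose replicate 9 in miR-196a-2-5p_+_1 (9.41, the others listed at 0).

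Other differences of the genotype effect between the sexes are medians of lists called at the preset correlation, none of which was called with an estimated correlation. Parentheses give a median without 1 library or under another setting where that moved it far. In liver mRNA, single Klk1b22 stood at −12.15 (WT females listed at 0, −7.53 with a pseudocount of 10), fatty acid synthesis genes at 1.36, cell cycle genes at 1.07, T cell genes at 0.60 (0.37 with a pseudocount of 10), endothelial genes at 0.60 and RNAs without a polyA tail at −0.91. Without WT male replicate 1, female-biased liver genes moved from 1.68 to 1.08 (0.89 with a pseudocount of 10), acute phase genes from −0.93 to −0.19 (−1.44 without WT male replicate 3), neutrophil genes from −2.16 to −0.48 and ER stress genes from −0.41 to −0.19. Male-biased liver genes stood at −1.21 (−0.76 without humanized male replicate 1) and extracellular matrix genes at 0.43 (0.66 without WT male replicate 3). Macrophage genes stood at 0.40 (0.23 without WT male replicate 2, 0.77 without humanized male replicate 2) and interferon genes at 0.38 (0.08 and 0.60 without humanized female replicates 1 and 3). Genes of fatty acid oxidation stood at −0.37 (−0.24 without WT female replicate 2, −0.58 without humanized female replicate 1).

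In adipose mRNA many lists depended on WT male replicates 4 or 5, the only WT males. Without WT male replicate 5 hepatocyte genes turned from −1.72 to 1.70 (−5.64 without WT male replicate 4), male-biased liver genes from −1.90 to 0.33 (−5.64), xenobiotic genes from −1.31 to 0.30 (−3.96), genes of bile acids and sterol transport from −1.04 to 1.58 (−4.95, and −1.67 with a pseudocount of 10) and mitochondrial respiration genes from 0.19 to −0.03 (0.39). Without the same library erythrocyte genes moved from −2.62 to −1.44, acute phase genes from −1.98 to −0.41, plasma cell genes from −1.80 to −0.54, fatty acid synthesis genes from 0.77 to 0.47, adipocyte genes from 0.19 to 0.01 (0.61 without humanized male replicate 4) and T cell genes from 1.02 to 1.75 (0.48 without WT male replicate 4). Without WT female replicate 4 thermogenic genes moved from 1.08 to 0.21 and skeletal muscle genes from 2.10 to 0.11 (3.25 without humanized male replicate 6). Without humanized male replicate 4 mesothelial genes moved from −2.06 to −1.13, cell cycle genes turned from 0.52 to −0.13 (1.05 without humanized male replicate 5) and neutrophil genes moved from −1.10 to −3.00 (−0.71 without humanized female replicate 4). ER stress genes stood at −0.30 (−0.18 without humanized male replicate 6).

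In small RNA, let-7 stood at 0.13 in liver (0.08 without WT male replicate 5, 0.22 without WT female replicate 2) and −0.15 in adipose tissue (−0.04 after rescaling). In adipose tissue immune cell miRNAs stood at 0.56 and pancreas miRNAs at −2.40 (0.32 and −1.04 with the batch-corrected values), erythrocyte miRNAs at −1.16 (−0.72 without WT male replicate 6) and liver-enriched miRNAs at −0.23 (−0.07 without WT female replicate 10, −0.37 without WT male replicate 9, −0.08 with a mean of at least 100, −0.37 without the covariate). miR-34 and ciliated cell miRNAs stood at 2.08 (1.00 without WT female replicate 10, 0.53 under the replicate block). Cyp17a1 stood at −3.12 in the liver and 5.97 in the adipose tissue of females, and the difference between the tissues was not tested.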

How the results depend on the processing

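Tests on whole reads were planned and not run. Reads of mRNA were not recovered, and those of small RNA could be recovered only for features with at least 10 reads. The mean of at least 100 and the features without a shifted start were chosen after seeing the data. Of the named results, 366 in liver mRNA, 397 in adipose mRNA, 104 in liver small RNA and 150 in adipose small RNA, called were 103, 33, 24 and 41, and kept under every alternative 69, 21, 14 and 19. Reversed somewhere were 4, 8, 2 and 1, and the cause was not tested for any change given here.

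With a pseudocount of 10 the calls were 8 for liver mRNA in males (5 in the main analysis), 5 in females (3) and 15 for adipose small RNA in males (8), liver As3mt by sex was 0.0679 (−1.24) and liver Borcs7 by sex of animal −0.0175 (0.05). After rescaling Borcs7 for sex was −0.0017, Cela2a −0.0187 (0.03), and adipose small RNA in males gave 0 calls, as it did without a filter, without the run covariate and without shifted starts. Without a covariate liver mRNA by sex gave 2 calls and the sex comparison 33 in liver and 65 in adipose small RNA. With the batch-corrected values liver small RNA gave 48 sex calls, miR-200b-5p 0.0265 (−0.66), and adipose small RNA in males 23, 8 of them shared. Without shifted starts the sex comparison gave 85 in adipose small RNA.

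Replicate numbers were not taken as pairs, as the lowest correlation of same-numbered libraries was −0.455 in liver mRNA, −0.105 in adipose mRNA, −0.403 in liver small RNA and −0.223 in adipose small RNA, and 2 of 12, 7 of 11, 7 of 21 and 0 of 20 libraries correlated best with their own number. In adipose mRNA same-numbered libraries correlated at a mean of 0.146 and others at −0.073, so that shared handling was not excluded there. Under the replicate block liver mRNA gave 3 calls in males and 2 over both sexes, liver small RNA 38 by sex of animal, adipose small RNA 0 in males and 72 by sex of animal, and adipose miR-34a-5p in males −0.44 (0.31). In adipose small RNA WT and humanized males shared only the number 9. The blocked male differences there thus rest mostly on links through female libraries.

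With the correlation of lists estimated, the called lists went from 19, 10, 11, 15 and 9 of 37 to 0, 0, 0, 0 and 2 in liver mRNA (males, females, both, by sex, sex). They went from 16, 19, 17, 18 and 13 of 39 to 0 in each in adipose mRNA, from 0, 3, 2, 1 and 4 of 11 to 0 in each in liver small RNA, and from 5, 4, 3, 6 and 5 of 13 to 0, 0, 1, 0 and 0 in adipose small RNA.

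With each library left out in turn, liver mRNA calls ran from 3 (without WT male replicate 1 or humanized male replicate 1) to 15 (WT male replicate 3) in males, 2 to 6 in females, 2 to 7 over both sexes, 0 to 10 by sex and 854 (humanized female replicate 3) to 1544 for sex. Sdhd in males ran from −0.0404 to 0.45 and Borcs7 for sex from −0.0595 to 0.14, Cela2a for sex from −0.31 to 0.50. Adipose mRNA calls ran from 2 to 8 in males, 2 to 8 in females, 3 to 7 over both sexes, 0 to 6 by sex and 39 to 91 for sex. In adipose mRNA Trib3 in males ran from −0.64 to 0.0335, Cyp7b1 from −4.46 to 0.92, Cd4 from −0.28 to 2.03, Kdm5d in females from −2.74 to 0.20, Ass1 over both sexes from −2.02 to 0.0844, Borcs7 by sex from −0.21 to 0.39, Borcs7 for sex from −0.0262 to 0.27 and Arg1 for sex from −0.44 to 2.96. Small RNA calls ran from 0 to 1 in liver males, 50 to 135 for sex in liver, 0 to 25 in adipose males, 0 to 8 over both sexes and 73 to 161 for sex in adipose tissue, and liver miR-34a-5p over both sexes from −0.0336 to 0.27.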

Other observations

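The metallothionein genes in this part were singled out only after their values were seen, while their list and its tests were planned. Metallothionein genes, which bind metals and are induced by them, were compared in male adipose tissue. Mt1 stood at 25373 ± 15435 in WT males (n = 2) and 5153 ± 894 in humanized males (n = 3), with females at 5331 ± 154 and 4852 ± 1315 (male log2 difference −2.17, limma adjusted p = 0.174). Mt2 stood at 20009 ± 14353 and 2980 ± 1396 in males and 2912 ± 252 and 2618 ± 1256 in females (−2.63, limma adjusted p = 0.249), and the small heat shock gene Hspb1 at 18047 ± 101 and 11648 ± 1187 in males (−0.64, limma adjusted p = 0.194). Among the 19 measured metallothionein and heat shock genes these 3 were lower when adjusted over the list alone, with 0 called over all genes by limma, and the list was not called (adjusted p = 0.329, adjusted p = 0.826 with an estimated correlation). The WT male values rest on 2 animals.

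The Hoxa10 signal of female gonadal fat paired with a neighbouring miRNA, as Hoxa10 was 1222 ± 93.8 in WT females and 3.18 ± 1.55 in WT males, and miR-196b, whose gene lies beside Hoxa10, was 11187 ± 1985 and 273 ± 153. Humanized animals showed the same, with Hoxa10 at 1110 ± 213 in females and miR-196b-5p at 13715 ± 3900.

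Other splits of the samples were run as tests of chance, by exchanging genotype or sex labels, and all of them were planned before their results were seen. Each count below is given with the real value and, in parentheses, the highest other value. The real mRNA gene counts by genotype in males, in females and over both sexes include As3mt and Borcs7, which were replaced by design. A low share of splits there thus says little of genotype differences in other genes. For liver mRNA genotype in males, 2 of 10 splits called at least the real 5 genes (highest other 5) and 2 of 10 at least the real 19 lists (19), and in females 2 of 10 called at least 3 genes (3) and 5 of 10 at least 10 lists (16). With 10 splits these shares are too few for one under 0.05. Over both sexes 5 of 100 splits called at least 5 genes (8) and 52 at least 11 lists (18), and by sex 33 of 100 called at least 1 gene (7) and 17 at least 15 lists (18). Sex called 1456 genes in 1 of 100 splits, the real one (highest other 32), with 81 splits at or above 9 lists (21).

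For adipose mRNA in females, 3 of 10 splits called at least 3 genes, with up to 14 in another split, and 1 of 10 at least the real 19 lists (highest other 16). A split that calls several times the real count may come from a structure among the samples or from chance, which was not tested further. Over both sexes 3 of 100 splits called at least 4 genes (7) and 36 at least 17 lists (22). The real 4 were As3mt, Borcs7 and the nearby Gm6967 and Cyp17a1. For sex 1 of 100 called at least 73 genes (34) and 69 at least 13 lists (25). Adipose mRNA in males and by sex was not split, because WT males number 2.

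For liver small RNA in males 100 of 100 splits called at least the real 0 features by limma (highest other 5) and 100 at least 0 lists (8), in females 100 called at least 0 features (1) and 13 at least 3 lists (4), over both sexes 100 called at least 0 (1) and 53 at least 2 lists (6), and by sex 100 called at least 0 (0) and 83 at least 1 list (7). Sex called 77 features in 1 of 100 splits (highest other 3) and at least 4 lists in 9 (6). For adipose small RNA in males 5 of 100 splits called at least 8 features (14) and 23 at least 5 lists (8), in females 100 called at least 0 (1) and 35 at least 4 lists (7), over both sexes 100 called at least 0 (13) and 56 at least 3 lists (7), and by sex 100 called at least 0 (8) and 12 at least 6 lists (7). Sex called 130 features in 1 of 100 splits (highest other 1) and at least 5 lists in 30 (9). Every split calls at least 0, so the counts beside a real 0 were fixed in advance and say nothing of chance. Where lists were called, the preset correlation thus called as many under other splits nearly everywhere.

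The labelled preparation left 0 genes called by limma between the 2 kinds of liver mRNA library (659 at an unadjusted limma p under 0.05 of 15180), and RNAs without a polyA tail had a median difference of −0.04, 6 of 12 lower in polyA libraries. The sequencing run called 152 features (18.2%) in liver and 297 (22.9%) in adipose small RNA. The replicate of each group cannot be matched between mRNA and small RNA, so the paired mRNA and miRNA values were compared by group only.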
